A study of Mus musculus with 6 samples.

How the data were processed

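The series measured gene expression in mammary epithelial cells of pregnant mice carrying a floxed insulin receptor gene, either with or without a Cre recombinase transgene driven by the promoter of beta-lactoglobulin, a milk protein gene. Per the labels' protocols, cells were prepared by collagenase digestion on day 13.5 of pregnancy from 3 mice of each genotype, and each mouse gave 1 Affymetrix MoGene 1.0 ST array. Groups and mouse numbers were taken from the sample titles, which number the Cre- mice 1, 2 and 4 and the Cre+ mice 5, 6 and 7. The labels give no scan date, litter or processing batch, so no batch could be entered in any fit.

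The deposited intensity of each probe set on each array was, per the labels, made by robust multi-array averaging (RMA) over core exons with the Expression Console software. The software version, genome build and annotation version are not given in the sources used here. The deposited intensities were on a linear scale, from 18.7 to 10919, and the per-array columns of the authors' comparison table held the same values, with a largest difference of 0 between the tables. The design fixed in advance had assumed log2 values, so log2 was taken first. No intensity lay below 18.7, and a constant may have been added before deposit, which no source states. If so, the fold changes of dim genes are understated here, and an alternative took 16 off every value before log2. The deposited p-values in the authors' table were, per the file headers, from a test per probe set, and a recomputation of an equal-variance test on the linear intensities matched 100% of them within 2e-04. The deposited fold column was a ratio of the Cre+ mean to the Cre- mean, and recomputation matched 100% of the values within 0.01. The 4 columns of group means and errors in that table were not used.

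Of 28853 probe sets, 2936 had no gene name, 2933 named several genes and 22984 named 1 gene. Among the last, 24 names had been turned into calendar dates by a spreadsheet and were kept as they stood, 21919 matched a RefSeq gene by symbol or synonym, and 2425 received a newer symbol for matching to the gene lists. Gene names in the text are those of the array unless a newer symbol is stated. No genome of a known build accompanies the values, so no coordinates are given. Probe sets naming 1 gene with a mean log2 intensity at or above the 30th percentile of all probe sets (log2 4.48, linear 22.4) were tested, which left 16921 probe sets of 15343 genes. Dim genes below that level were not tested.

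Cre+ was compared with Cre- with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of adjusted p under 0.05. A log2 change is Cre+ minus Cre-, with the standard error (SE) from the moderated fit. A member of a gene list was represented by its probe set with the highest mean. The 26 gene lists, the tests, the filter, the alternative settings not marked otherwise and the rule for named genes were fixed before the data were examined. The lists cover insulin and IGF signalling, FoxO targets repressed by insulin, milk proteins, fatty acid and triglyceride synthesis, cholesterol synthesis, lactose synthesis and glucose supply, glycolysis and the pentose phosphate pathway, prolactin-Jak2-Stat5 signalling, the cell cycle, endoplasmic reticulum folding, amino acid transport and synthesis, ribosomal proteins, oxidative phosphorylation, the interferon response, immediate early and stress genes, and 11 cell types. Each list was tested with camera at a preset inter-gene correlation of 0.01, which compares its members with all other genes, again with an estimated correlation, and with fry, which asks whether its members moved in a common direction. Camera was also run on ranks. These p-values were adjusted over the 26 lists, and those of lists added after the result was seen over the added lists alone. The mean log2 level of each list on each array was also compared between the groups, with a 95% interval and an exact permutation test, two-sided, whose smallest possible p is 0.1 with 3 against 3 arrays.

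The named genes were Insr, the 10 genes with the largest rise and the 10 with the largest fall among those past the adjusted threshold (1 small nucleolar RNA was skipped by the rule), the 3 members of each list with the smallest p, and Igf1r, Irs1, Irs2, Srebf1, Stat5a, Elf5, Akt1 and Prlr. A gene named outside this rule is said to have been chosen after its values were seen.

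The fit was tested on simulated data for the same comparison, with 16921 probe sets and a known subset shifted. It recovered 74% of probe sets shifted by 0.5 on the log2 scale and 99% of those shifted by 1, and 8.33% of its calls were false. The simulated values were drawn independently for each probe set and array, without correlation between genes or shared array effects. These rates may therefore not hold for the real arrays. The alternatives were no intensity filter, a filter at the 50th percentile, centring each array on its median, quantile normalization, eBayes without the trend or with robust variances, array quality weights, unnamed probe sets included, 1 probe set per gene, an equal-variance test per probe set, fold thresholds, and each array left out in turn. After the data had been seen, fits were added with 16 taken off, without the arrays Cre- 1 and Cre+ 7 (those with the most lymphocyte transcripts in their group), with the lymphocyte marker level or the level of 10 luminal structural genes as a covariate, and with the deposited p-values adjusted. Precision is limited by the number of arrays, 3 per group.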

Results

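Mammary epithelial cells from 3 IRfl/fl Cre- mice, which keep the insulin receptor, were compared with cells from 3 IRfl/fl Cre+ mice, which express Cre recombinase from the promoter of a milk protein gene, on day 13.5 of pregnancy. At this stage the alveolar epithelium is beginning secretory differentiation, the acquisition of milk protein and lipid synthesis before birth. After RMA, which normalizes arrays to one another, the 6 arrays had closely similar intensity distributions, with medians between 28.4 and 29.3 linear units. Pairwise correlations between arrays across genes lay between 0.969 and 0.993. The first principal component, with 43.4% of the variance, separated the genotypes. The second, with 33.6%, set Cre- 1 (score 21.1) and Cre+ 7 (13.7) apart from the other arrays, which scored between -14.6 and -3.06. These are also the 2 arrays with the highest mean level of T and B cell markers in their group, at log2 6.46 and 5.81.

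The first question was whether the targeted transcript was lower in Cre+ cells. Insr fell by 0.95 (SE 0.15, n = 3 and 3) on the log2 scale at probe set 10576692, 1.93-fold, with adjusted p = 0.0231. At the second Insr probe set, 10576696, the change was -0.52 (SE 0.09), 1.43-fold, with adjusted p = 0.0285. All 3 Cre+ values lay below all 3 Cre- values at both probe sets (exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). In the authors' deposited table the ratios were 0.52 and 0.70. The labels do not give the position of the probes relative to the deleted part of the gene, and probes outside it would not measure the deletion. The call at the main probe set was lost without Cre- 2 (adjusted p = 0.0785), Cre- 4 (0.0602), Cre+ 5 (0.0909) or Cre+ 6 (0.0782).

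The comparison of all genes asked which transcripts differed between the genotypes. Genes of milk proteins, among them Lalba, Wap and Spp1, had the largest falls, while the largest rises included the cell cycle genes Ccnd1 and Mcm6 and the matrix genes Vcan and Mgp. Of 16921 tested probe sets, 706 passed adjusted p under 0.05 in limma, with 344 rises and 362 falls over 671 genes. Among these, 19 rises and 40 falls reached 2-fold. At an unadjusted p under 0.05 there were 3384 probe sets, against 846 from chance alone. The groups did not overlap at 25.7% of the probe sets, where chance gives 10%. The count depended on single arrays, with 46 probe sets without Cre+ 5, 52 without Cre+ 6, 118 without Cre- 2, 265 without Cre- 4 and 291 without Cre+ 7. Of 59 called named genes other than Insr, 12 passed whichever array was left out, namely Atp2c2, Btn1a1, Creld2, Gpd1, Hsph1, Lalba, Mfge8, Pfkl, Slc34a2, Spp1, Thrsp and Vcan. A further 12 passed under 4 or 5 of the 6 omissions, 31 under 1 to 3, and Pf4, Pkm2, Rpl18 and Rpl28 under 0.

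Lalba, which encodes alpha-lactalbumin, the regulatory subunit of lactose synthase, fell by 3.69 (SE 0.26), 12.9-fold, the largest fall, with adjusted p = 0.00258. Wap, the gene of whey acidic protein, fell by 2.75 (SE 0.42), 6.72-fold. Spp1 (osteopontin) fell by 2.43 (SE 0.25), 5.39-fold, and Pigr, the receptor that carries immunoglobulin A into milk, fell by 2.03 (SE 0.24), 4.08-fold. The other genes among the 10 largest falls were Hephl1 (-1.91), a copper-dependent ferroxidase, Dkkl1 (-1.83), Fabp3 (-1.65), a fatty acid carrier, Atp2c2 (-1.50), a Golgi calcium pump, Ltf (-1.48), the lactoferrin gene, and Cel (-1.44), a milk lipase. Retnla, which encodes a small secreted protein, had the largest rise among named genes past the adjusted threshold, by 1.96 (SE 0.33), 3.90-fold, with 1 small nucleolar RNA above it left out by the naming rule. Vcan, the gene of the matrix proteoglycan versican, rose by 1.87 (SE 0.10), 3.65-fold. The next were the vault RNA Vaultrc5 (1.67), Mgp (1.52), an extracellular matrix protein, Ccnd1 (1.49), the cyclin D1 gene, and Id4 (1.36), an inhibitor of helix-loop-helix transcription factors. Slfn3 (1.28), Hells (1.23), Pdpn (1.22) and Mcm6 (1.18) completed the 10. Slfn3 has close relatives, and shared hybridization between them was not tested.

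**Figure D1:**
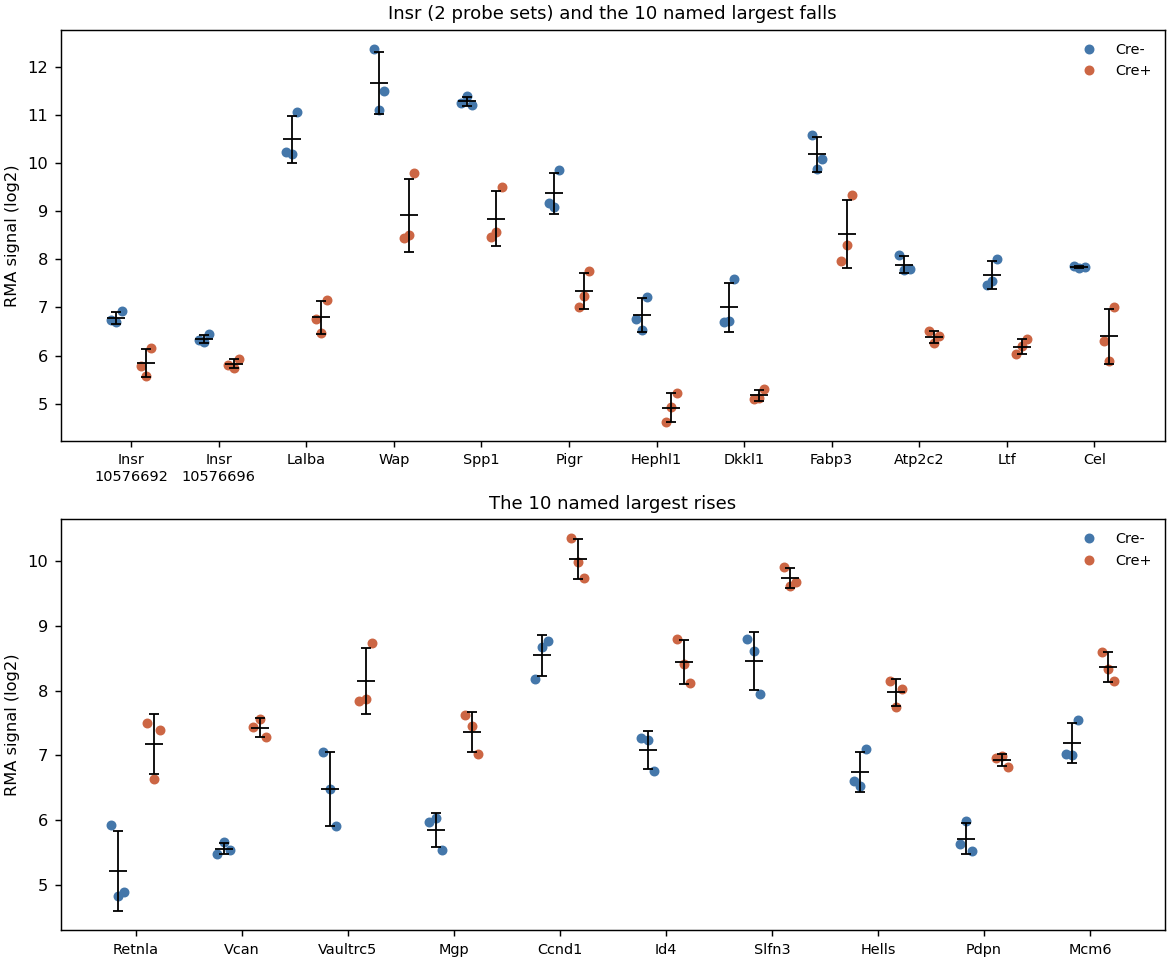
RMA signal (log2) of Insr and of the genes with the 10 largest falls (top) and 10 largest rises (bottom) on each of the 3 Cre- and 3 Cre+ arrays. Points are arrays, and the bars give the group mean with 1 SD. Lalba went from a mean of 10.49 in Cre- to 6.79 in Cre+, and Vcan from 5.56 to 7.43.

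Of 22 measured milk protein genes, 16 fell and none rose (17 and 0 adjusted over the list alone). Beside Lalba, Wap, Spp1, Pigr, Ltf and Cel these included Mfge8 (-1.07, SE 0.10), a milk fat globule membrane protein, and Btn1a1 (-1.18, SE 0.12), the butyrophilin gene needed for milk fat secretion. The list's median change was -0.62, with camera adjusted p = 1.18e-17 and fry adjusted p = 0.00727, but adjusted p = 0.239 with an estimated correlation. The number that fell was 7 without Cre- 2, 5 without Cre+ 5 and 4 without Cre+ 6, and 15 without Cre- 1 and Cre+ 7 together. On the same arrays the mean of the luminal alveolar markers differed by -0.57 (95% interval -0.94 to -0.19). That mean is not independent of the milk proteins, since 4 genes, Lalba among them, are in both lists and all 4 fell. Caseins are named here after their values were seen. Csn3 fell by 0.66 (SE 0.10) and Csn1s1 by 0.37 (SE 0.06), while Csn2, at a log2 level of 12.63 in Cre- cells and close to the top of the array's range, changed by -0.10 (SE 0.07, adjusted p = 0.494).

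Of 15 genes of lactose synthesis and glucose supply, 3 fell and none rose (7 and 0 adjusted over the list alone). They were Lalba, B4galt1 (-0.73, SE 0.13), the catalytic subunit of lactose synthase, and Slc5a1 (-0.42, SE 0.09), a sodium-glucose cotransporter. The list had camera adjusted p = 0.000184 and fry adjusted p = 0.0141, with adjusted p = 0.239 with an estimated correlation. Its median change was only -0.14, against a mean of -0.44. Lalba, the gene with the largest fall, is also in the milk protein and luminal alveolar lists, and the list was not tested without it. The list also shares 3 genes with the glycolysis list. The number that fell was 5 without Cre- 1 and 1 without each of Cre- 2, Cre+ 5 and Cre+ 6. Of 22 glycolysis and pentose phosphate genes, Pfkl (-1.18, SE 0.11), a phosphofructokinase, Pgd (-0.52, SE 0.09) and Pkm2 (-0.35, SE 0.07; now Pkm) fell and none rose. Adjusted over the list alone, 10 fell and 1 rose. For this list camera adjusted p was 1.32e-05 and fry adjusted p 0.0308, with adjusted p = 0.335 with an estimated correlation. The number that fell was 6 without Cre- 1 and 1 without any other single array. It was 9 with array weights or the lymphocyte covariate and 7 without Cre- 1 and Cre+ 7 together. It was 2 without the intensity filter, with median centring, robust variances, unnamed probe sets or the luminal covariate.

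Among 35 fatty acid and triglyceride synthesis genes there were 12 falls and 1 rise (21 and 2 adjusted over the list alone), and 28 of the 35 had a change below 0. Thrsp, a regulator of lipogenesis, fell by 0.99 (SE 0.08), Gpd1, which makes glycerol 3-phosphate, fell by 1.22 (SE 0.10), and Plin2, a lipid droplet coat protein, fell by 0.73 (SE 0.08). The gene that rose was Dgat2 (0.70), an enzyme of triglyceride synthesis, named after its value was seen. In camera the adjusted p was 1.30e-09 and in fry 0.00727, with adjusted p = 0.166 with an estimated correlation. The number that fell was 3 without Cre- 2, 5 without Cre- 4, and 2 without Cre+ 5 or Cre+ 6. On the arrays of these falls, and of those in the lactose, glycolysis and FoxO lists, the mean of the luminal alveolar markers differed by -0.57 (95% interval -0.94 to -0.19) and that of the basal markers by 0.45 (0.06 to 0.84). Among 26 cholesterol synthesis genes 3 rose and 1 fell (5 and 2 adjusted over the list alone). Idi1 (0.76, SE 0.15) and Sc4mol (0.71, SE 0.14; now Msmo1) rose, as did Stard4 (0.59), a sterol carrier named after its value was seen, and Hsd17b7 fell by 0.53 (SE 0.11). The list's camera adjusted p was 0.0372, with adjusted p = 0.762 with an estimated correlation and 0.505 in fry, and the call was lost without Cre- 1 (0.333), Cre+ 5 (0.209) or Cre+ 6 (0.0540) and with the lymphocyte covariate (0.169). Without Cre- 2, Cre+ 5 or Cre+ 6 none of its genes passed, and without Cre- 4 or Cre+ 7 a single gene rose.

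Of 41 cell cycle genes, 9 rose in Cre+ cells and none fell (16 and 0 adjusted over the list alone). Beside Ccnd1 and Mcm6, these included Pcna (0.81, SE 0.10), the sliding clamp of DNA polymerases, Mcm4 (0.98, SE 0.12) and Mcm3 (0.91, SE 0.12), subunits of the replicative helicase. The cell cycle list had camera adjusted p = 7.11e-10, with adjusted p = 0.490 with an estimated correlation and 0.223 in fry. The mean of the list on each array differed by 0.41 between the groups (95% interval -0.14 to 0.96, exact permutation p = 0.2). On the same arrays the mean of the basal markers differed by 0.45 (95% interval 0.06 to 0.84) and that of the fibroblast markers by 0.50 (-0.21 to 1.21). The number of rises was 3 without Cre- 2 and 0 without Cre+ 5 or Cre+ 6, and 10 without Cre- 1 and Cre+ 7 together.

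Of 31 insulin and IGF signalling genes, only Insr and Igf2r (-0.61, SE 0.09), the receptor that clears IGF2, passed the test, both lower (2 also adjusted over the list alone). Igf2 changed by 0.28 (SE 0.08, adjusted p = 0.116). Neither camera (adjusted p = 0.498) nor fry (0.421) called the list, and both calls were lost without Cre- 2, Cre- 4, Cre+ 5 or Cre+ 6. Changes that did not pass were 0.31 for Igf1r, the IGF1 receptor, 0.41 for Irs1, -0.04 for Irs2, -0.10 for Akt1 and -0.34 for Srebf1, a lipogenic transcription factor (SE 0.10, 0.17, 0.15, 0.07 and 0.18). Of 25 genes that FoxO factors activate and insulin represses, 5 fell and none rose (7 and 0 adjusted over the list alone). They were Sesn3 (-0.76, SE 0.11), a stress-inducible regulator of mTORC1, Cited2 (-0.68, SE 0.10), Insr itself, Pink1 (-0.44) and Gabarapl1 (-0.58), the last pair named after their values were seen. Insr is the targeted gene, and the list's mean and tests below include it. Less repression by insulin would raise such genes. The 5 called genes fell, but 20 were not called and 11 of the 25 had a change above 0. Whether repression by insulin differed was not tested. The list's mean change was -0.18 and its median -0.02, with camera adjusted p = 0.0182, fry 0.00727, and adjusted p = 0.293 with an estimated correlation. The camera call was also lost on ranks (adjusted p = 0.105) and without Cre- 1 (0.0803). The number was 1 without Cre- 2, 2 without Cre- 4, 3 without Cre+ 7 and 0 without Cre+ 5 or Cre+ 6.

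Of 21 prolactin-Jak2-Stat5 genes, Ccnd1 and Cav1 (0.73, SE 0.14), the caveolin that restrains Jak2, rose and Elf5 (-0.43, SE 0.09, adjusted p = 0.0462), a transcription factor of alveolar differentiation, fell. Adjusted over the list alone 2 rose and 4 fell. The list's median was -0.10 and its mean 0.00, with camera adjusted p = 0.505 and fry 0.707. Stat5a changed by -0.48 (SE 0.13, adjusted p = 0.0838) and Prlr, the prolactin receptor, by -0.17 (SE 0.10, adjusted p = 0.411), neither past the test. The Elf5 call was lost when any array other than Cre- 1 was left out, without the intensity filter and with the luminal covariate. No gene of the list passed without Cre+ 5 or Cre+ 6.

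Of 27 endoplasmic reticulum folding genes, the chaperones Creld2 (0.94, SE 0.08) and Sdf2l1 (0.55, SE 0.11) rose and Xbp1 (-0.52, SE 0.09), a transcription factor of the unfolded protein response, fell (8 and 1 adjusted over the list alone). Camera gave adjusted p = 0.00874, with adjusted p = 0.490 with an estimated correlation and 0.0988 in fry, and the call was lost without Cre+ 5 (0.0577) and with the luminal covariate (0.134). When any array other than Cre- 1 was left out, 1 gene passed. No gene of amino acid transport and synthesis passed among 21 (0 also adjusted over the list alone; camera adjusted p = 0.505, fry 0.683), and the smallest p belonged to Sesn2 (-0.24), Phgdh (-0.21) and Slc7a1 (0.29). Among 30 ribosomal protein genes Rpl18 (0.29, SE 0.06) and Rpl28 (0.32, SE 0.07) rose, 2 also adjusted over the list alone, a call that neither kept when any array was left out, and Rps3 (0.27) did not pass (camera adjusted p = 0.536, fry 0.683). Among 35 oxidative phosphorylation genes Sdha (-0.57, SE 0.09), a subunit of succinate dehydrogenase, fell, a call lost without Cre- 2, Cre+ 5, Cre+ 6 or Cre+ 7, and Ndufa9 (-0.34) and Cycs (0.35) did not pass (2 falls and 1 rise adjusted over the list alone; camera adjusted p = 0.138, fry 0.511). Of 28 interferon response genes none passed (0 also adjusted over the list alone; camera adjusted p = 0.588, fry 0.878), with Cxcl10 at 0.26, Rsad2 at 0.14 and Oas3 at 0.09. Of 27 immediate early and dissociation stress genes, Hsph1 (0.77, SE 0.08), a heat shock protein, rose, and Nr4a1 (0.34) and Hspb1 (0.32) did not pass (2 rises adjusted over the list alone; camera adjusted p = 0.137, fry 0.212).

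**Figure D2:**
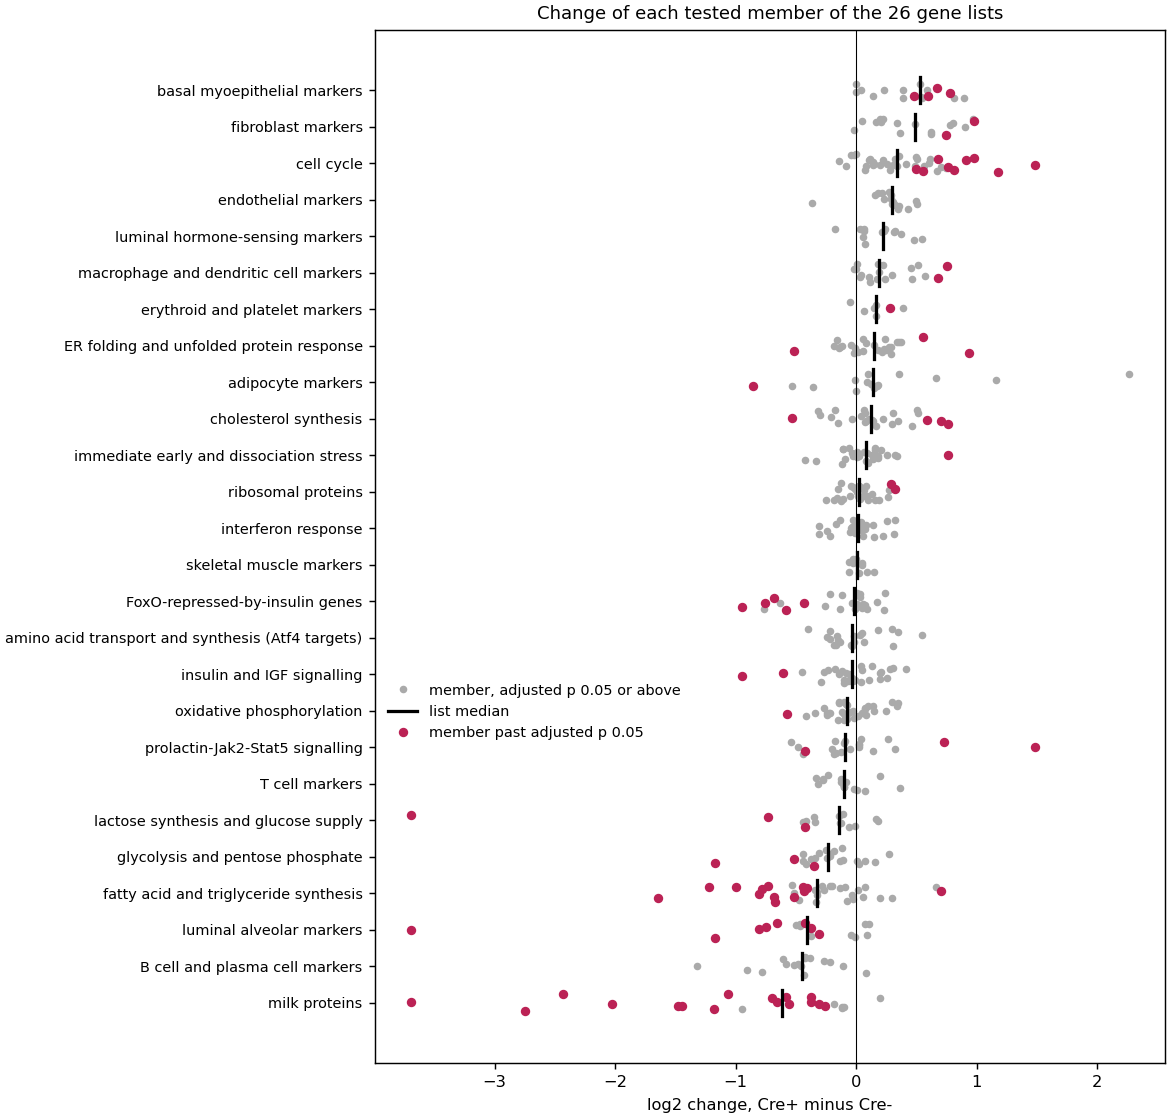
Log2 change (Cre+ minus Cre-) of each tested member of the 26 gene lists, ordered by list median. Each point is a gene, red where it passed adjusted p 0.05, and black bars are list medians, from -0.62 for milk proteins to 0.53 for basal myoepithelial markers.

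A collagenase digest can hold several cell types, so their markers were compared in the same way. Of 18 luminal alveolar markers, 8 fell and none rose (8 and 0 adjusted over the list alone), among them Lalba, Slc34a2 (-1.17, SE 0.08), a phosphate transporter, and Folr1 (-0.75, SE 0.10), the folate receptor. The list shares 4 genes with the milk proteins, all of which fell, and 4 of its other 14 genes fell. Camera gave adjusted p = 2.04e-07 and fry 0.0197, with adjusted p = 0.319 with an estimated correlation, and the number was 2 without Cre- 2, Cre+ 5 or Cre+ 6, 5 without Cre- 4 and 4 without Cre+ 7. Of 17 basal myoepithelial markers, 4 rose and none fell (11 and 0 adjusted over the list alone), among them Trp63 (0.67, SE 0.12), the basal transcription factor p63, Mylk (0.78, SE 0.14) and Krt17 (0.48, SE 0.09). Camera gave adjusted p = 2.04e-07, with adjusted p = 0.360 with an estimated correlation and 0.0785 in fry, and 2 rose without Cre- 1, 1 without Cre- 2, Cre- 4 or Cre+ 7, and 0 without Cre+ 5 or Cre+ 6. None of 14 luminal hormone-sensing markers passed (0 also adjusted over the list alone), with Pgr, the progesterone receptor gene, at 0.23, Tbx3 at 0.22 and Cited1 at 0.31. That list's camera adjusted p was 0.00288, with adjusted p = 0.345 with an estimated correlation and 0.0785 in fry. The mean of 10 genes of luminal epithelial structure, among them keratins 8 and 18 and chosen after the data were seen, differed by -0.26 (95% interval -0.83 to 0.30, exact permutation p = 0.3), and 0 of them passed.

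Of 17 fibroblast markers, Mfap5 (0.75, SE 0.13) and the fibronectin gene Fn1 (0.98, SE 0.21) rose (4 and 0 adjusted over the list alone), and Dcn (0.97, SE 0.22) did not pass. Camera gave adjusted p = 1.62e-05, with adjusted p = 0.490 with an estimated correlation and 0.223 in fry. The number of rises was 9 without Cre- 1, 1 without Cre+ 7 and 0 without any other array. Of 19 macrophage and dendritic cell markers, the complement genes C1qc (0.75, SE 0.16) and C1qb (0.68, SE 0.14) rose (2 and 0 adjusted over the list alone), and Cd163 (0.17) did not pass. In camera the adjusted p was 0.00869, with adjusted p = 0.762 with an estimated correlation and 0.505 in fry, and the call was lost without Cre- 4 (0.385) or Cre+ 7 (0.0942). The number was 4 without Cre- 1, 1 without Cre- 4 and 0 without any other array. None of 16 endothelial markers passed (0 also adjusted over the list alone), with Emcn at 0.50, Vwf at 0.30 and Tie1 at 0.43 (camera adjusted p = 0.00447, fry 0.449, and adjusted p = 0.702 with an estimated correlation), and the camera call was lost without Cre- 4 (0.111) or Cre+ 7 (0.0707). With the lymphocyte covariate 10 of 16 endothelial, 12 of 17 fibroblast, 7 of 19 macrophage and 11 of 17 basal markers rose. With the luminal covariate the camera directions of the endothelial (adjusted p = 0.851) and macrophage (0.439) lists reversed. The fibroblast median then went from 0.49 to 0.15 and the basal median from 0.53 to 0.41. Of 7 erythroid and platelet markers Pf4 (0.28, SE 0.05), a platelet chemokine, rose, a call lost whichever array was left out, and Gp9 (0.15) and Ppbp (0.17) did not pass. Adjusted over the list alone 4 rose (camera adjusted p = 0.00447, fry 0.0541, and adjusted p = 0.335 with an estimated correlation), and with the filter at the 50th percentile the camera call was lost (0.479).

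Of 16 adipocyte markers Cidea (-0.86, SE 0.11), a lipid droplet protein also made by lactating epithelium, fell, while Lpl (-0.53, SE 0.12) and Car3 (2.26, SE 0.60) did not pass (2 rises and 2 falls adjusted over the list alone; camera adjusted p = 0.141, fry 0.667). The Cidea call was lost without Cre+ 5 or Cre+ 6. No T cell marker among 16 passed (0 also adjusted over the list alone; camera adjusted p = 0.505, fry 0.877), with Thy1 at 0.36, Zap70 at -0.10 and Cd247 at -0.10, but 10 fell with the luminal covariate. No B cell or plasma cell marker among 16 passed (0 also adjusted over the list alone), with Igj (now Jchain) at -1.32 (SE 0.51), Fcrla at -0.42 and 2010001M09Rik (now Mzb1) at -0.42. For that list camera adjusted p was 0.0372, with adjusted p = 0.762 with an estimated correlation, and the direction was the opposite without Cre- 1 (adjusted p = 0.634). With the luminal covariate 15 of the 16 fell, and the camera call was lost without Cre+ 5 (0.225) or Cre+ 6 (0.0964), with the 50th percentile filter (0.114), median centring (0.0563), eBayes without the trend (0.0807) and array weights (0.0590). None of 10 skeletal muscle markers passed (0 also adjusted over the list alone; camera adjusted p = 0.601, fry 0.707), with Mylpf at 0.05, Tnni2 at 0.09 and Mb at 0.15.

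**Figure D3:**
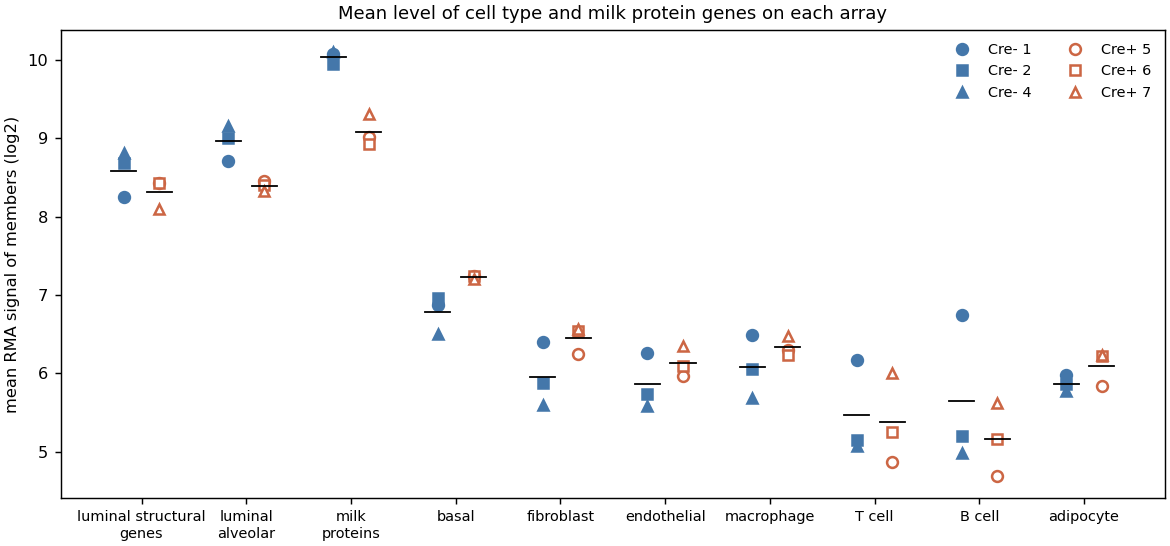
Mean RMA signal (log2) of the members of cell type and milk protein lists on each array, with short bars for the group means. Milk protein means lie between 8.93 and 9.31 in Cre+ and between 9.95 and 10.11 in Cre-, while T and B cell means are highest on Cre- 1 and Cre+ 7.

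Of the 26 lists, 16 passed adjusted p under 0.05 in camera with the preset correlation, 9 upward and 7 downward. With an estimated correlation 0 passed, and on ranks 1 of the 16 calls, that of the FoxO list, was lost. With fry 6 passed, all downward, namely the milk protein, luminal alveolar, fatty acid, lactose, glycolysis and FoxO lists. The FoxO list includes the targeted gene Insr, and the lactose list includes Lalba, which is also in the milk protein and luminal alveolar lists.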

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

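The tests with 16 taken off, without Cre- 1 and Cre+ 7, with a lymphocyte or luminal covariate and with the deposited p-values adjusted were chosen after the result was seen. The 706 probe sets became 1437 with array quality weights (704 of the 706 among them), 1795 with the lymphocyte level and 1479 with the luminal structural level as a covariate, 313 with a change of at least 1.5-fold, 34 from the deposited p-values adjusted over the 16921 tested probe sets (10 adjusted over all 28853) and 1 from the equal-variance test per probe set. The cause was not tested. With 1 array left out the count lay between 46 (without Cre+ 5) and 781 (without Cre- 1), and fewer samples were then tested. Under the other filters, scalings, variance models and choices of probe set, and without Cre- 1 and Cre+ 7 together, the adjusted count lay between 536 and 954. The unadjusted count of 3384 became 1232 with at least 1.3-fold. The Insr change lay between -1.11 and -0.82 with 1 array left out, always downward, with adjusted p between 0.0187 and 0.0909, and kept its call under every limma alternative with all 6 arrays. Of the 26 lists 16 passed camera with the preset correlation, 0 with an estimated correlation and 6 with fry. The directions of the endothelial (adjusted p = 0.851) and macrophage (0.439) lists reversed with the luminal covariate, and the cause was not tested. With that covariate 15 of 16 B cell markers (median change -1.19) and 10 of 16 T cell markers (-0.57) fell, where none had passed. The calls of 5 named genes (Elf5, Slc5a1, Hsd17b7, Pkm2 and Pf4) were lost with it, while 11 other named genes gained a call. With the lymphocyte covariate 10 of 16 endothelial markers rose (median 0.45), where none had passed. The FoxO list's camera call was lost on ranks (adjusted p = 0.105) and without Cre- 1 (0.0803), and calls of the cholesterol, endoplasmic reticulum, endothelial, macrophage, B cell and erythroid lists were also lost under at least 1 other setting. The B cell list reversed without Cre- 1 (adjusted p = 0.634), the array with its highest marker level, and its adjusted p lay between 0.000256 and 0.634 over the left-out arrays. No called named gene reversed with an array left out. No paired analysis was possible because the groups share no mouse numbers. Signal over background limits dim genes, whose changes a constant in the intensities would understate.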

Other observations

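The 6 gene lists of the next 2 paragraphs, the 10 luminal structural genes and all tests of the 3 patterns were chosen after the result was seen, and only the counts over other splits of the arrays were planned. Genes named from these 6 lists outside the naming rule were also chosen after their values were seen. Because these lists were assembled once the changed genes were known, their counts and p-values are not independent evidence. Their fry and camera p-values were adjusted over these 6 lists alone, so they cannot be set beside those of the lists fixed in advance. Before adjustment, camera with an estimated correlation gave p = 0.0114 for the lysosomal list and 0.00989 for the transport list below. The fatty acid synthesis list, fixed in advance, had a smaller p of 0.00639 in that test, yet adjusted p = 0.166. Of 27 genes of mitochondrial and peroxisomal fatty acid oxidation, 12 fell and none rose (22 and 0 adjusted over the list alone), and all 27 had a change below 0. Ehhadh, the peroxisomal bifunctional enzyme, fell by 1.22 (SE 0.10), Acadsb by 0.74 (SE 0.09) and Cpt1a, the carnitine palmitoyltransferase that admits fatty acids to mitochondria, by 0.72 (SE 0.12). The list had fry adjusted p = 0.00293, with adjusted p = 0.0551 with an estimated correlation in camera. The number was 2 without Cre- 2, 3 without Cre- 4 or Cre+ 7 and 1 without Cre+ 5 or Cre+ 6. Of 53 genes of lysosomal enzymes and the proton pump, 11 fell and none rose (22 and 0 adjusted over the list alone), with the cathepsin genes Ctsl (-1.01, SE 0.10) and Ctsh (-0.56, SE 0.07) in front (fry adjusted p = 0.00164, and adjusted p = 0.0342 with an estimated correlation). That number was 1 without Cre- 2 or Cre+ 5, 2 without Cre- 4 or Cre+ 6 and 5 without Cre+ 7, and 2 rose with the lymphocyte covariate and 1 without Cre- 1 and Cre+ 7 together. Of 19 calcium, phosphate and zinc transport genes, 6 fell and none rose (9 and 0 adjusted over the list alone), including Slc34a2, Atp2c2 and the zinc transporter Slc39a7 (-0.69, SE 0.10), with fry adjusted p = 0.000359 and adjusted p = 0.0342 with an estimated correlation. It was 2 without Cre- 2, Cre+ 5 or Cre+ 6 and 3 without Cre- 4 or Cre+ 7. On the same arrays as these 3 groups of falls, the mean of the luminal alveolar markers differed by -0.57 (95% interval -0.94 to -0.19) and that of the basal markers by 0.45 (0.06 to 0.84). The transport list shares 2 genes with the luminal alveolar list.

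Of 46 extracellular matrix genes 11 rose and none fell (21 and 3 adjusted over the list alone), while 2 fell with array weights, with the lymphocyte covariate or without Cre- 1 and Cre+ 7 together, and 1 with the luminal covariate or without Cre- 1. Has2, a hyaluronan synthase, rose by 0.99 (SE 0.08), Reln by 1.00 (SE 0.17) and Mmp2, a matrix metalloprotease, by 0.95 (SE 0.12), beside Vcan and Mgp. The list had fry adjusted p = 0.00493 and adjusted p = 0.0681 with an estimated correlation. On the same arrays, which also gave the DNA replication rises below, the fibroblast marker mean differed by 0.50 (95% interval -0.21 to 1.21). The matrix and fibroblast lists share 3 genes. The basal marker mean differed by 0.45 (0.06 to 0.84). The number was 6 without Cre- 2 or Cre+ 7, 4 without Cre- 4 and 2 without Cre+ 5 or Cre+ 6. Of 46 DNA replication genes 22 rose and none fell (31 and 0 adjusted over the list alone), among them Uhrf1 (0.85, SE 0.16), Asf1b (0.80, SE 0.15) and Rpa2 (0.63, SE 0.09), with fry adjusted p = 0.00624 and adjusted p = 0.0764 with an estimated correlation. The number was 10 without Cre+ 7, 2 without Cre- 2 and 0 without Cre+ 5 or Cre+ 6. None of 31 mitosis genes passed the adjusted threshold in limma (0 also adjusted over the list alone; fry adjusted p = 0.602, camera adjusted p = 0.0128, and adjusted p = 0.620 with an estimated correlation), with Bub1 at 0.51, Mad2l1 at 0.54 and Cdk1 at -0.01, while 2 rose with the luminal covariate and 1 without Cre- 4.

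The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 706 probe sets past the adjusted threshold, and 1 of the 10 splits, the real one, gave as many, with 0 as the highest of the others. For the unadjusted count this was 3384 against 1255, and for the lists called by camera 16 against 15, again with 1 of 10 as large. The camera count of lists is thus nearly matched by the split that sets Cre- 1, Cre+ 6 and Cre+ 7 against the rest. With fry that split called 0 lists, against 6 for the real split.

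The lower milk protein transcripts may come from fewer luminal epithelial cells in the Cre+ digests or from less milk gene expression per cell. Given the level of the luminal structural genes on each array, the genotype difference of the milk protein mean was -1.04 (95% interval -1.51 to -0.58), against -0.96 without that term. This fit cannot decide on a lower luminal share, because the luminal level did not track the milk protein mean within a genotype. Cre+ 7 had the lowest luminal level (8.10) but the highest milk protein mean of the Cre+ arrays (9.31). A lower luminal share stays open. A smaller alveolar fraction among luminal cells stays open, since 4 of the 14 luminal alveolar markers that are not also in the milk protein list fell, and saturation of caseins was not tested, while with 16 taken off before log2 the milk protein genes that fell still numbered 16 of 22. Loss of Insr, the difference that the design names, stays among the open explanations and was not tested, as does delayed alveolar growth. All mice are IRfl/fl and the series has no Cre+ group with an unfloxed receptor gene. Loss of Insr therefore cannot be told apart from any other effect of the Cre transgene.

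The higher DNA replication transcripts could come from an array-wide shift after abundant milk transcripts fell, from more stromal and basal cells, or from more cells in S phase. Normalization holds the median change of all probe sets (0.0037) near 0, so that first test was void and was replaced, with all list values known, by the lists fixed in advance, of which 12 of the 25 other than the cell cycle list had a 95% interval of the mean change wholly below that of the replication list (0.47, 0.20 to 0.73). Of these 12, 6 had intervals that held 0, at mean log2 levels from 4.90 to 10.38 around the replication list's 6.40, and the rest had means that fell. With the median held near 0, one rise of all genes alike could not show in these lists either, so they cannot test it. A shift of part of the genes stays open. Given the mean of the fibroblast and basal markers, the difference was 0.69 (95% interval 0.41 to 0.97) for the replication list. It was 0.91 (0.53 to 1.29) for the cell cycle list, which was fixed in advance and without that term differed by 0.41 (-0.14 to 0.96). These lists share 13 genes. This fit cannot decide on those cells, because the basal means of Cre+ (7.20 to 7.25) all lay above those of Cre- (6.51 to 6.96). Among Cre- arrays, Cre- 4 had the lowest fibroblast (5.60) and basal means but the highest cell cycle mean (6.58), and with the term the difference grew. More stromal and basal cells stay open. The replication list exceeded the mitosis list by 0.30 (95% interval -0.18 to 0.79), so an equal rise of all cell cycle genes cannot be told apart from a rise of replication genes alone with 6 arrays, and more cycling cells of any type stay open.

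Of 35 fatty acid and triglyceride synthesis genes 12 fell and 1 rose, while of 26 cholesterol synthesis genes 1 fell and 3 rose. With an estimated correlation neither list's camera call held (adjusted p = 0.166 and 0.762). Fry called the fatty acid list (adjusted p = 0.00727) but not the cholesterol list (0.505). With the preset correlation, the fatty acid call held whichever array was left out, while the cholesterol call was lost without Cre- 1, Cre+ 5 or Cre+ 6. The difference between the mean changes of the lists was -0.48 (95% interval -0.82 to -0.14). The lists were paired after their changes had been seen, so this interval cannot decide on a common fall of all lipid synthesis genes. The cholesterol mean by itself changed by 0.15 (95% interval -0.15 to 0.45). Srebf1 itself did not pass the test, at -0.34 (adjusted p = 0.351).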
